A study of Drosophila melanogaster with 2 samples.

How the data were processed

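ChIP-seq peak lists were taken from 1 group, Hr83-GFP larvae, with biological replicates 3 and 4, numbered as in the sample descriptions. Per the labels, whole larvae of pooled sexes expressed Hr83 with a C-terminal GFP, chromatin was sonicated, and the precipitation used an antibody against GFP. Nothing in the labels says more about how the replicates were obtained, and no p-value was computed across replicates.

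The authors deposited region lists in a narrowPeak layout without headers, for the assemblies dm6 and dm3: 1 relaxed list per replicate, 1 relaxed list called on both replicates pooled, and 1 thresholded list. Per the notes deposited with the samples, relaxed lists were called against a control alignment, and the thresholded list came from comparing both replicates' lists and the pooled list by irreproducible discovery rate (IDR). Every relaxed list held exactly 30000 regions. The aligner and the peak caller are not given in the sources used here. The deposited signal is the value per peak in the layout's signal column; it is the authors' own score, it is not normalized between lists, and it was used only to describe and rank peaks within a list. The deposited −log10 q-value per peak has a ceiling of 3.86 that 74.9% of the thresholded peaks share, so peaks were ranked by signal. No column held read counts, so the depth per sample is unknown. Intervals over peaks, windows or genes are 95% Clopper-Pearson intervals, and they cover counting error only.

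Peak positions on dm6 were compared with the genome sequence of the same assembly and the Ensembl release 115 annotation. Every region ended within its chromosome, and between 98.7% and 100% of the annotated coding transcripts on the plus strand of each chromosome began with ATG in the sequence. Only 2L, 2R, 3L, 3R, 4 and X were used. Coordinates are 1-based on dm6, and dm3 lists were compared by number, rank and signal, with no conversion of coordinates.

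Each summit was put in 1 class in the order promoter (within 500 bp of any annotated TSS), 5' UTR, coding exon, 3' UTR, noncoding exon, intron and intergenic. Shares were compared with the 25107 pooled regions that overlap no thresholded peak and with 100000 random positions. The trend of promoter share with signal was tested by permuting Spearman's rho with 100000 resamples. Replicates were compared by overlap of at least 1 bp between the 4797 strongest regions, beside 100 random shifts of the peaks along their chromosomes. Genes counted as carrying a peak when a summit lay within 1 kb of any TSS, and 21 gene lists were each tested against all other protein-coding genes with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment over the lists. The 21 motifs were searched on both strands in 200 bp windows and compared with random windows matched 1 to 1 on GC content in bins of 2 percentage points and on TSS distance class (within 500 bp, to 5 kb, beyond). Mean GC content was 44.7% in both sets. Motif hits within 50 bp of the summit among those within 250 bp were tested against 20% with an exact binomial test. Chromosome shares were tested against shares of TSSs with a two-sided Fisher's exact test. Log2 odds ratios have 0.5 added to each cell, and a test passed at an adjusted p below 0.05. Peaks and genes are not replicates, so these tests describe the peak list and not the variation between animals. Neighbouring genes that share a promoter peak were each counted.

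The gene lists, the motifs, the tests and the processing alternatives were fixed before the data were examined, except further draws of matched windows (1 over all peaks and 20 over peaks away from TSSs) and the tests of the closing observations. Of the list symbols, those of Hr46, Eip55E, Eip71CD, ImpL3, phm, Dl, apoLpp, plin1, plin2, Hsp67Bb and dbt were not matched in the annotation and were left out. The text names Hr83 and its relatives tll, dsf and Hr51; the nearest protein-coding gene within 5 kb of each of the 20 strongest peaks; and up to 4 members per gene list with the strongest peak within 1 kb of a TSS. Genes named outside this rule, in the closing observations, were chosen after their values were seen.

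Alternatives were the 2398 strongest peaks, TSS windows from 250 bp to 5 kb, other windows and comparison sets, other overlap rules, a logistic regression with gene length and number of TSSs, and the use of 1 replicate at a time, as its 4797 strongest regions. The procedures were tested on simulated data. Of 10 simulated lists of 25 genes with peaks at 60% of members against 27% elsewhere, over 13945 genes, 9 were called, and of 10 unchanged lists 0 were. A DRE planted in 5% of 4797 random windows was called and 0 of the 20 other motifs were. Simulated promoter peaks were recovered at 60.0% for 60.0% placed, and simulated shared peaks at 60.3% for 60.2% placed. Both were placed so that the rule would count them, which checks the counting only. Simulated genes were hit independently, without shared promoters or effects of gene length and TSS number, so false calls from these were not assessed. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.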

Results

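Chromatin occupancy of Hr83, an orphan nuclear receptor of the NR2E class, was profiled by ChIP-seq in whole wandering larvae of the last instar of Drosophila melanogaster. The larvae carried a transgene encoding Hr83 with GFP at its C-terminus, males and females were pooled, and chromatin was precipitated with an antibody against GFP. The series held 1 group, Hr83-GFP larvae, with 2 biological replicates that the labels number 3 and 4. The deposited lists gave peak positions and a signal per peak without read counts, so the sequencing depth is unknown and the intervals below cover counting error over peaks or genes only. With no other condition to compare, the design asks where the tagged receptor was found, how far the replicates shared their peaks, and which genes and sequences lay there.

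The thresholded list held 4797 peaks on dm6, and its strongest lay at the promoter of fkh (FBgn0000659), which encodes the forkhead transcription factor of the salivary gland and gut. That peak spanned 28585399 to 28585593 on 3R, with its summit 239 bp from the TSS and a signal of 1278, and it ranked 2 in replicate 3 and 1 in replicate 4. The next strongest peak lay at the promoter of CG14100 on 3L (19590498 to 19590743, signal 1264), followed by intronic peaks in osp (2L, 14685716 to 14685914, signal 1107), sbb (2R, 18337095 to 18337285, signal 1024) and CG13917 (3L, 1591763 to 1591991, signal 920). Among the 20 strongest peaks were also promoter peaks of Ugalt, a UDP-galactose transporter (signal 835), of the mitochondrial carrier gene aralar1 (694), of CG5335 (643), Tcs5 (636), CG1888 (617), PNPase (604) and CenG1A (593). A further peak lay 809 bp from the TSS of the vesicle coat gene Sec24AB (719). Intronic peaks in the same set lay in S, which encodes the EGF receptor pathway protein Star (675), in bun (655), in the junction gene cno (652), in ush (605) and in Krn (604). Of these 20 peaks, 2 had no protein-coding gene within 5 kb.

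The signal of all thresholded peaks ranged from 63.3 to 1278 with a median of 93.8, and the peaks covered 1168 kb, or 0.873% of the 133.9 Mb on the main chromosomes. Peaks of the full width of 256 bp made up 91.2% of the list. The 424 narrower peaks had a median width of 108 bp and a median signal of 223, against 89.6 at full width, and they made up 99 of the 100 strongest. All 4797 were the strongest regions of the relaxed list called on both replicates pooled.

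At the Hr83 gene itself (FBgn0037436, 3R, 6349243 to 6350512, plus strand), 0 thresholded peaks lay in the gene body and 3 lay within 5 kb of it. The strongest of these had its summit at 6350880, 1637 bp from the Hr83 TSS, with a signal of 186 and rank 435, and the others had signals of 98.7 and 67.4. All 3 lay within 500 bp of an annotated TSS other than that of Hr83, from which they were 1637 to 4856 bp away. The pooled relaxed list held 15 regions within 5 kb of the gene. The larvae carried an Hr83 transgene, and whether the 3 peaks reflect binding at the gene was not tested. Of the relatives of Hr83 in the NR2E class, dsf on 2L had 2 peaks within 5 kb (signals 130 and 92.5), both over 17 kb from its own TSS, and Hr51 on 2R had 1 peak downstream (signal 148, rank 821). The 2 dsf peaks ranked 4816 and 854 in replicate 3 and 407 and 3074 in replicate 4, so their order differed between the replicates. Near tll on 3R, 0 thresholded peaks and 0 regions of the relaxed lists were found within 5 kb.

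Peak summits were concentrated at promoters. A summit lay within 500 bp of an annotated TSS for 3086 peaks, 64.3% (95% Clopper-Pearson interval 63.0 to 65.7), against 28.7% of the 25107 other regions of the pooled relaxed list and 13.6% of 100000 random positions. The odds at the peaks exceeded those at the other regions by 2.16 ± 0.05 (SE) on the log2 scale, with a two-sided Fisher's exact p too small to be represented. By the same test, Fisher's exact, coding exons held 0.605% of the summits against 12.7% of the other regions (adjusted p = 4.67e-209), 3' UTRs 0.813% against 3.74% (adjusted p = 3.34e-33), introns 25.3% against 38.8% (adjusted p = 2.37e-73) and intergenic sequence 7.07% against 13.8% (adjusted p = 1.45e-42). The median distance from summit to nearest TSS was 119 bp at the peaks, 1369 bp at the other regions and 3340 bp at random positions. A distance of over 5 kb was found for 401 peaks, 8.36%.

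**Figure D1:**
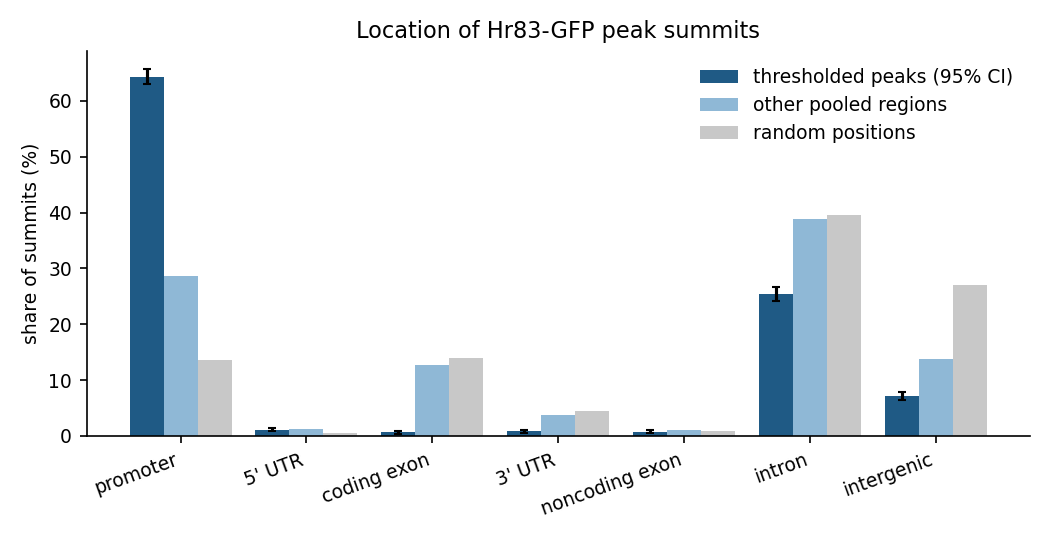
Share of summits in each annotated location (y axis, percent) for the thresholded peaks, with 95% intervals, the other regions of the pooled relaxed list, and random positions. Promoters, within 500 bp of a TSS, held 64.3% of the peaks against 28.7% and 13.6%, and coding exons 0.605% against 12.7%.

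Stronger peaks lay at promoters somewhat more often than weaker ones. From the strongest to the weakest of 5 equal bins, the promoter share was 69.5%, 66.9%, 66.0%, 62.1% and 57.0%. Spearman's rho between signal and promoter position was 0.08 across 4797 peaks, which are not independent replicates, and a permutation test with 100000 resamples gave p = 1e-05, the smallest it can give. Among the 100 strongest peaks 60 were at promoters (interval 49.7 to 69.7%), and among the 20 strongest 10 were; neither was tested against the rest.

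**Figure D2:**
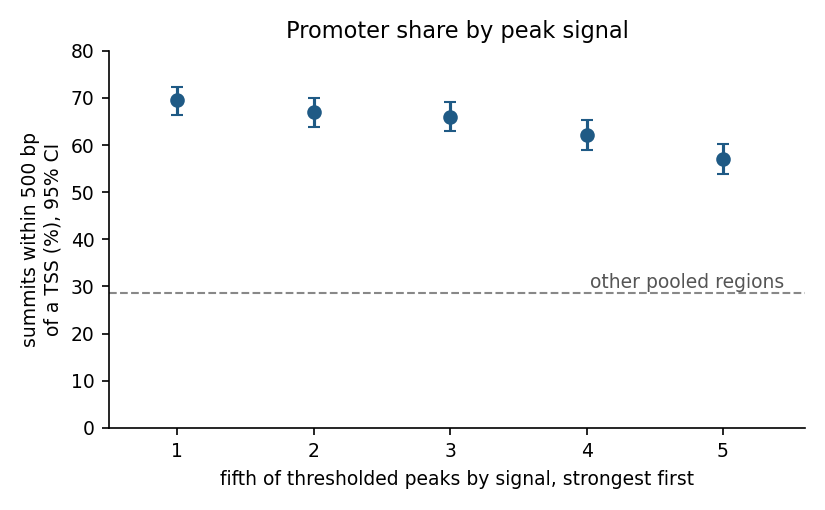
Share of summits within 500 bp of a TSS (y axis, percent, with 95% intervals) in 5 equal bins of the thresholded peaks ordered by signal, strongest first (x axis). The share went from 69.5% in the strongest bin to 57.0% in the weakest, and the dashed line marks 28.7% for the other regions of the pooled list.

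The replicates shared most of their strong peaks, fkh, CG14100, osp, sbb and CG13917 among them. Of the thresholded peaks, 76.3% (75.05 to 77.5) overlapped 1 of the 4797 strongest regions of replicate 3 and 80.6% (79.5 to 81.7) of replicate 4. Between the replicates, 62.1% (60.8 to 63.5) of the 4797 strongest regions of replicate 3 overlapped those of replicate 4, against 1.70% on average and 2.13% at most over 100 random shifts. In the complete relaxed lists of 30000 regions, 4690 thresholded peaks (97.8%) were found in both. Spearman's rho between the replicate signals was 0.40 across these 4690 peaks and 0.60 across all 14644 regions shared by the complete lists. The thresholded list was itself made from both replicates, so its overlap with each is not independent evidence. When at least 50% of both regions had to overlap, the share between replicates was 50.8%.

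Ribosomal protein genes carried peaks more often than other genes. A summit lay within 1 kb of a TSS for 3805 of 13945 protein-coding genes, 27.3%, and for 69 of 92 ribosomal protein genes, 75% (log2 odds ratio 3.00 ± 0.35 SE, Fisher's exact test adjusted over 21 lists, p = 3.75e-20). The strongest of these were at RpL7 (signal 587), RpS27 (480), RpL32 (372) and RpL41 (346). By the same Fisher's exact test, higher shares were also found for genes of the ecdysone response (17 of 27, adjusted p = 5.81e-04), led by vri (219), crol (193), Eip74EF (168) and Hr39 (156), for cell cycle genes (13 of 23, adjusted p = 0.0143), led by dup, Dp, stg and E2f2, and for genes that pattern the imaginal discs (22 of 46, adjusted p = 0.0143), led by dac (308), Dll (270), ush (178) and ey (164). The lead of vri rested on replicate 4, where its peak ranked 92. In replicate 3 it ranked 1719, behind Eip74EF (711), crol (715) and Hr39 (1302). Heat shock genes followed with 10 of 17 (Fisher's exact test, adjusted p = 0.0277), led by Hsp83 (374), Hsp27 (359), Hsp68 (238) and Hsp23 (168), and nuclear receptor genes with 11 of 21 (adjusted p = 0.0328), led by Hr96 (297), ERR (169), Hr39 and Hr78 (153). The nuclear receptor and ecdysone lists share members such as Hr39.

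Receptor genes of the sensory neurons, cuticle genes and midgut genes carried peaks less often. Of 179 odorant and gustatory receptor genes 3 had a peak (Or9a, Ir60e and Gr64a, log2 odds ratio -4.27 ± 0.78, Fisher's exact test, adjusted p = 9.43e-20), of 122 cuticle protein genes 2 (Lcp9 and Cpr73D, -4.19 ± 0.92, adjusted p = 1.51e-13), and of 25 midgut digestive enzyme genes 1 (Jon65Ai, adjusted p = 0.0176). The other 12 lists did not pass. Salivary glue genes, secreted by the larval salivary gland, had a peak at 6 of 11 (Fisher's exact test, adjusted p = 0.155), with a signal of 240 at a peak shared by Sgs5 and Sgs5bis, 217 at Sgs1 and 81.3 at Sgs8. Fat body genes had 7 of 14 (Fisher's exact test, adjusted p = 0.149), led by bmm (180) and Lpin (152), and glial genes 5 of 11 (adjusted p = 0.298), led by moody (335) and loco (315). Proteasome genes had 18 of 48, led by Rpn5 (234) and Rpt5 (217), oxidative phosphorylation genes 28 of 84, led by COX6B (181), circadian genes 5 of 13 and Enhancer of split genes 4 of 11. Neuronal genes had 4 of 26 (elav, Csp, Syx1A and Rbp9), muscle genes 3 of 20 (Tm1, Msp300 and Mef2), ecdysteroid synthesis genes 2 of 13 (mld and Npc1a), hemocyte genes 1 of 13 (srp) and Hox genes 1 of 8 (Abd-B).

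With gene length and number of TSSs in a logistic regression (n = 13945 genes), the ribosomal protein, heat shock, sensory receptor and cuticle lists passed. In it, the ecdysone response (n = 13945 genes, adjusted p = 0.229), cell cycle (0.0615) and imaginal disc (0.527) lists did not pass. Nor did the nuclear receptor (0.595) and midgut (0.133) lists. Above other genes, the glue (0.0118) and proteasome (0.0385) lists passed in this regression, at log2 odds ratios of 2.57 and 1.07. Below other genes, the neuronal (0.00655) and muscle (0.0148) lists passed in it, at -2.64 and -2.68. From replicate 4 alone the heat shock (0.0535) and midgut (0.0752) lists did not pass, from replicate 3 alone the heat shock (0.0611), imaginal disc (0.590) and nuclear receptor (0.233) lists did not, and the fat body list passed from either (2.83e-04 and 0.0457). In a 5 kb window the ecdysone response (0.141), imaginal disc (0.317), nuclear receptor (0.349), heat shock (0.141) and midgut (0.141) lists did not pass, and from replicate 3 alone the ecdysone response fell to a log2 odds ratio of 1.38 (0.0457). With the 2398 strongest peaks the imaginal disc (0.119) and midgut (0.0518) lists did not pass while the oxidative phosphorylation (0.0196) and fat body (0.0353) lists did, and the heat shock list did not in a 500 bp window (0.0897) or over the gene body (0.0805).

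**Figure D3:**
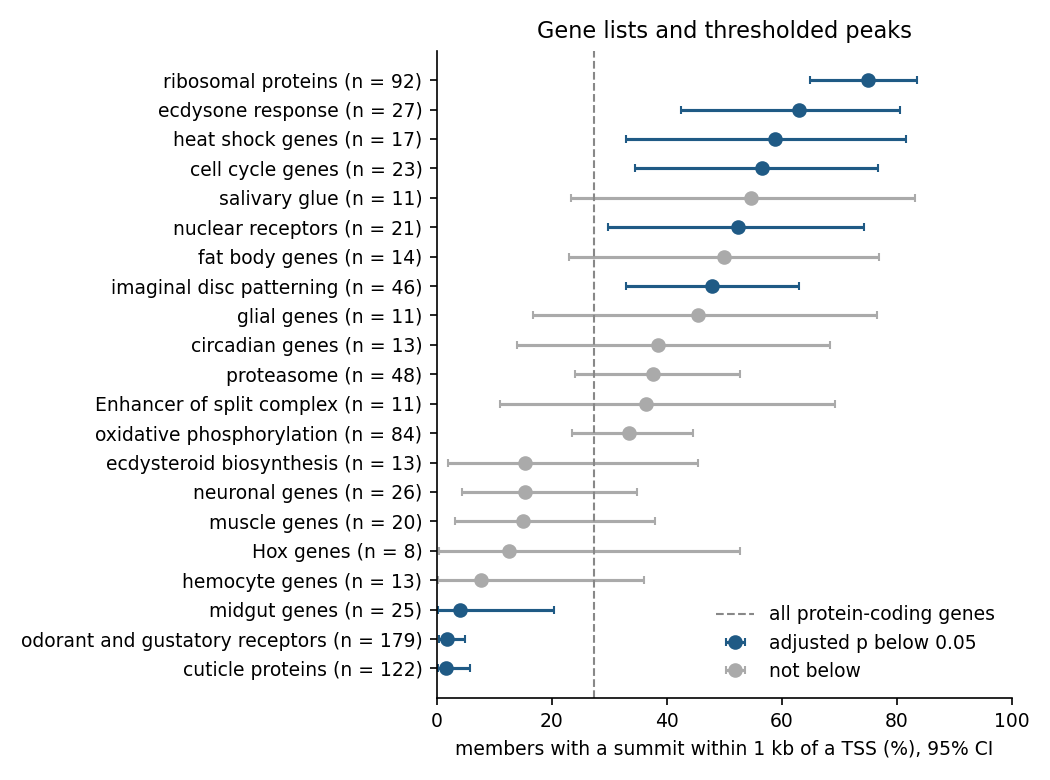
Percent of members of each gene list with a thresholded summit within 1 kb of a TSS (x axis), with 95% Clopper-Pearson intervals. Dark points have an adjusted p below 0.05, and the dashed line marks 27.3% of all protein-coding genes. Ribosomal protein genes lie highest at 75% and cuticle protein genes lowest at 1.64%.

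In sequence, promoter elements and repeats were more frequent at the peaks than in matched windows, and the nuclear receptor motifs searched were not. Other nuclear receptor sites were not searched. With 1 group, what is particular to Hr83-GFP at these peaks was not tested. The windows were matched on GC content and TSS distance class, and within 500 bp of a TSS the exact distance was not matched. Of all peaks 47.3% lay within 100 bp of a TSS, so an excess of core promoter elements may reflect closeness to the TSS. In 200 bp windows at the summits, the GAGA element GAGAGAG, bound by Trl, was found at 11.97% of peaks against 3.42% of matched windows (log2 odds ratio 1.94 ± 0.13, Fisher's exact test, adjusted p = 6.48e-57). The DRE element TATCGATA of housekeeping promoters was found at 6.48% against 1.46% (2.22 ± 0.19, Fisher's exact test, adjusted p = 1.05e-37), Motif 1 of core promoters, GTCACACT, at 3.84% against 1.04% (adjusted p = 6.67e-19), CA repeats at 10.6% against 5.23% (adjusted p = 1.46e-21), the CTCF motif at 12.1% against 7.82% (adjusted p = 9.90e-12) and the BEAF dual core at 0.271% against 0.0208% (adjusted p = 0.00477). The hexamer AAGTCA known for NR2E receptors was found at 8.65% against 10.3% (-0.28 ± 0.10, Fisher's exact test, adjusted p = 0.0101) and the hexamer AGGTCA shared by many nuclear receptors at 3.00% against 4.92% (-0.74 ± 0.16, adjusted p = 5.99e-06). A scrambled form of the NR2E hexamer, ACATGA, was also rarer at peaks, at 5.65% against 7.42% (Fisher's exact test, adjusted p = 0.00154). The extended form AAAAGTCA was found at 1.38% against 1.52% (Fisher's exact test, adjusted p = 0.639), and the EcR-Usp type palindrome at 1 peak and 1 matched window.

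Of the 21 motifs, 10 were more frequent at peaks and 5 less frequent, the others of these being Su(Hw), AP-1, Grainyhead and GATA above and Su(H) and Scalloped below. By the same Fisher's exact test with another draw of the matched windows, chosen after seeing the data, Su(Hw) (adjusted p = 0.188), Grainyhead (0.482) and GATA (0.119) did not pass, and among the 2398 strongest peaks AP-1 (0.788), Su(H) (0.0667), Scalloped (0.0802) and BEAF (0.0654) did not. Among these strongest peaks the log2 odds ratio of AP-1 was 0.16, against 0.46 over all peaks. Those of BEAF (3.70 against 3.17), Su(H) (-0.29 against -0.27) and Scalloped (-0.31 against -0.24) were no smaller in size. At the 1711 peaks over 500 bp from a TSS, DRE (Fisher's exact test, adjusted p = 0.937) and Motif 1 (0.910) did not pass. By the same Fisher's exact test, BEAF (1), ACATGA (-0.02, 1), Su(H) (0.505) and Scalloped (0.913) did not pass. AGGTCA, at a log2 odds ratio of -0.43, did not pass (Fisher's exact test, adjusted p = 0.159). AAGTCA, also at -0.43, did (Fisher's exact test, adjusted p = 0.0212). Against 20 further draws of matched windows, chosen after seeing the data, AAGTCA at these peaks had a log2 odds ratio of -0.16 ± 0.12 (Fisher's exact test, p = 0.190), and at all peaks it did not pass in 100 bp windows (adjusted p = 0.970) or against flanking windows (0.214).

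**Figure D4:**
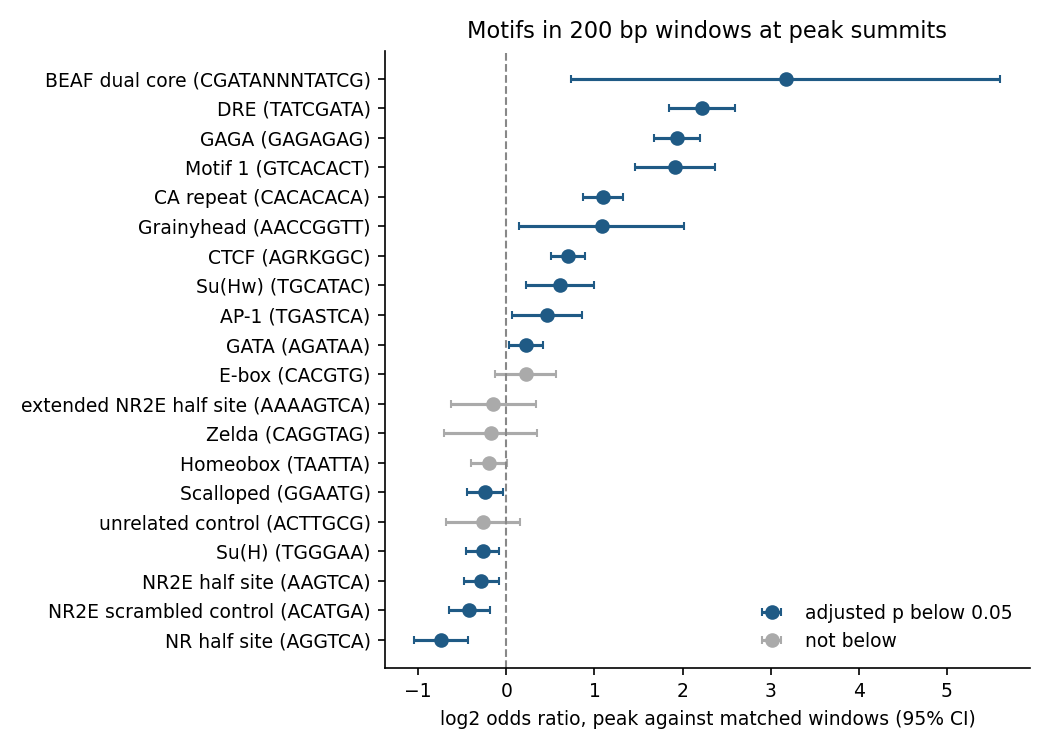
Log2 odds ratio of each motif in 200 bp windows at thresholded summits against matched windows (x axis), with 95% intervals; the EcR-Usp palindrome, with 1 hit on each side, is left out. Dark points have an adjusted p below 0.05. DRE, GAGA and Motif 1 lie at 2.22, 1.94 and 1.91, and AGGTCA lies lowest at -0.74.

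Several of these motifs sat at the summit. Of the DRE hits within 250 bp of a summit, 49.7% (237 of 477) were within 50 bp, against 20% for even spread (exact binomial test, adjusted p = 4.82e-46). No matched windows were used here, so changes of base composition or TSS distance from summit to flank were not accounted for. By the same exact test, the share was 43.8% for Motif 1 (adjusted p = 4.83e-18), 33.7% for CTCF (3.38e-27), 28.3% for GAGA (1.25e-14), 24.6% for CA repeats (8.92e-05) and 64.7% for the BEAF dual core (11 of 17, 2.27e-04). Homeobox motifs (11.98%, exact test, adjusted p = 1.49e-15) and GATA motifs (17.1%, adjusted p = 0.0115) lay away from summits. It was 22.1% for AAGTCA (exact test, adjusted p = 0.168) and 18.1% for AGGTCA (adjusted p = 0.543), neither past the threshold. CA repeats did not pass within 25 bp of the summit (adjusted p of 0.589) or from replicate 3 alone (0.272), and GATA did not within 25 bp (0.301).

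By chromosome, X carried fewer peaks than its share of TSSs. It held 635 peaks, 13.2% (12.3 to 14.2), against 16.6% of TSSs (log2 odds ratio -0.38 ± 0.07, Fisher's exact test, adjusted p = 3.20e-08). Of all regions of the pooled relaxed list 12.4% lay on X, so the lower share was not particular to the thresholded peaks. Arm 3L held 21.2% against 19.3% (0.18 ± 0.06, Fisher's exact test, adjusted p = 0.00556), a difference that did not pass among the 2398 strongest peaks (adjusted p = 0.306) or against chromosome length (0.698). Arms 2L (19.0% against 19.5%), 2R (21.3% against 20.6%), 3R (24.7% against 23.3%) and 4 (0.521% against 0.776%) did not pass. Among the 2398 strongest peaks 3R was above (0.18, adjusted p of 0.0319) and 4 below (-0.98, 0.0485), and against chromosome length 4 was below (-0.93, 0.00175).

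On the older assembly dm3 the thresholded list held 4794 peaks, and its strongest had a signal of 1274 against 1278 on dm6. Taken rank by rank, the dm3 signals were 0.977 of the dm6 signals in the median.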

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

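The thresholded list on dm3 held 9 of its 4794 peaks on Uextra, a collection of sequence not placed on a chromosome in that assembly, which the dm6 comparisons do not use. They were flagged against a count of 0, which is no expected count for dm3. The pooled relaxed list on dm3 also had 45 of its 30000 regions off the main chromosomes, so such regions were not particular to the thresholded list. The strongest of the 9 had a signal of 229 and rank 222 on dm3, and the genomic origin of these sequences was not analysed here.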

How the results depend on the processing

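The other draw of matched windows was chosen after seeing the data and the other alternatives before. The promoter share kept its excess in all 8 alternatives, 7 against the other regions and 1 against random positions, from 57.2% in a 250 bp window to 73.9% in a 1000 bp window, and was 62.4% to 63.0% from 1 replicate alone. The trend of promoter share with signal kept its direction in either replicate (rho 0.08 and 0.11). Its permutation p stayed at the smallest value the resampling can give, so p cannot show whether the trend changed. The cause of the changes below was not tested. The read depth is unknown, so what it limits was not assessed.

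With overlap of at least 50% of both regions, 69.6% of the thresholded peaks were found in replicate 3 and 73.7% in replicate 4, and 50.8% of the replicate 3 regions in replicate 4. With summits within 150 bp, the last share was 60.6%. Among the 1000 strongest, 78.6% of the thresholded peaks were found in replicate 4 and 58.9% of the regions in both replicates.

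A TSS window of 5 kb left 2 gene lists above the rest, ribosomal protein and cell cycle. The log2 odds ratio of the glial list was -0.28 in a 500 bp window, and that of the circadian list -0.31 with gene length and TSS number. Neither list passed in any of these.

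The number of motifs above matched windows was 6 with the 2398 strongest peaks, 100 bp windows or flanking windows, and 6 to 11 from 1 replicate alone. The number below was 3 with the 2398 strongest peaks and 2 at peaks over 500 bp from a TSS. The log2 odds ratio of Homeobox was 0.0085 with the 2398 strongest peaks, but it was below matched windows and passed in 6 of the 8 alternatives, at -0.24 from either replicate alone, -0.29 with the other draw, -0.51 in 100 bp windows, -0.55 over 500 bp from a TSS and -0.64 against flanking windows. Grainyhead and GATA did not keep their call in 6 of the 8, Su(Hw) in 5, and AP-1, Su(H) and Scalloped in 4. At peaks over 500 bp from a TSS, Grainyhead, GATA, Su(Hw) and AP-1 kept theirs. In 100 bp windows the log2 odds ratio was 0.020 for AAGTCA, 0.22 for AAAAGTCA and 0.25 for the unrelated control motif, which had 0.019 in 400 bp windows. GATA, above matched windows, was below flanking windows at -0.19 (adjusted p of 0.0384). At peaks over 500 bp from a TSS, Zelda had 0.81 and the unrelated control 0.14. AAAAGTCA had -0.041 to 0.074 from 1 replicate alone.

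AGGTCA lay away from the summit from replicate 4 alone (-0.44, adjusted p of 0.0096). Within 25 bp of the summit, 1 motif lay away from it, and the log2 ratio to even spread was -0.32 for AAAAGTCA, -0.44 for Grainyhead and 0.26 for the unrelated control. From 1 replicate alone it was -0.17 to 0.23 for E-box, -0.21 to 0.062 for Scalloped and -0.0070 to 0.039 for the unrelated control.

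Against chromosome length, 2 arms were above and 2 below, with 2R at 0.22 and 2L at 0.14. With the 2398 strongest peaks 2 were below, and 2L had 0.045. From 1 replicate alone 1 to 2 were above, with 3R at 0.16 from replicate 3, and 2R had -0.019 to 0.074.

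Of the alternatives for single lists, motifs, centred motifs and arms that kept their direction, 118, 117, 53 and 14 kept their side of the threshold, 19, 35, 3 and 2 no longer passed, and 8, 7, 1 and 5 newly passed.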

Other observations

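The tests in this part were chosen after the peaks had been seen, and the rescaling of X is the 1 test whose result had not been seen when its outcome was predicted. Genes in this part that the naming rule does not cover were chosen after their values were seen. Several long genes carried many peaks along their length. Within the gene body and 1 kb around it, Eip75B, a nuclear receptor gene induced by the moulting hormone ecdysone, held 22 peaks over 114 kb, sbb 18, tara 17, the ecdysone receptor gene EcR 15, Eip74EF and ush 14 each, and br, the Broad transcription factor gene, 13. Mur2B, whose span contains br, also held 14. The 27 ecdysone response genes held 118 peaks, against 35.9 ± 11.7 (SD) in 10000 random lists matched on gene length (two-sided resampling test, n = 27 genes, adjusted p = 8.40e-04 over 21 lists), and Eip75B, EcR, Eip74EF and br held 64 of the 118. Against lists matched on gene length and number of TSSs, the mean was 39.3 ± 10.9 for the ecdysone response genes (n = 27, adjusted p = 8.40e-04) and 26.4 for the nuclear receptor genes (n = 21, adjusted p = 0.00350). These counts of peaks differ from the share of genes with any peak, for which neither list passed with gene length and TSS number (0.229 and 0.595). Nuclear receptor genes held 66 peaks against 23.6 (n = 21, adjusted p = 0.00210), 37 of them at Eip75B and EcR, which are on both lists. Without these genes the nuclear receptor list did not pass (29 against 18.9, n = 19, adjusted p = 0.182), and the ecdysone list without its 4 did (54 against 26.9, n = 23, adjusted p = 0.0336). Of the 21 lists, 8 passed above and 4 below in the test matched on gene length. Ribosomal protein genes held 98 against 26.7 (n = 92, adjusted p = 8.40e-04), fat body genes 23 against 9.38 and oxidative phosphorylation genes 47 against 26.3 (n = 14 and 84, adjusted p = 0.00577 each). The cell cycle (n = 23, adjusted p = 0.0107), heat shock (n = 17, adjusted p = 0.0113) and proteasome (n = 48, adjusted p = 0.0157) lists were also above, and hemocyte genes held 1 against 9.77 (n = 13, adjusted p = 0.0145). Neuronal genes held 6 against 29.9, cuticle protein genes 5 against 34.4 and sensory receptor genes 9 against 65.3 (n = 26, 122 and 179, adjusted p = 8.40e-04 each, from a raw p of 2e-04, the smallest these draws can give). Imaginal disc genes held 46 against 51.3 (n = 46, adjusted p = 0.815).

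Of 3815 protein-coding genes with a TSS within 500 bp of a divergent neighbour's, 45.1% had a peak, against 20.6% of 10130 other genes. The 1 kb window credits a gene with its neighbour's peak, and a peak at either of 2 unlinked promoters would be expected for 36.9% with no preference; the remaining difference was not tested. A summit within 500 bp of the TSS was found for 24.2% of protein-coding genes, 5.52% of 290 tRNA genes (3.19 to 8.81), 2.84% of the 211 tRNA genes over 1 kb from a protein-coding TSS, 8.55% of 269 snoRNA genes and 8 of 32 snRNA genes. Around Hr83, the body and 5 kb on each side held 1.33 relaxed pooled regions per kb against a median of 0.298 over protein-coding genes, a density at percentile 99.9 of all genes, at 99.9 in replicate 4 and at 93.1 in replicate 3. The larvae carried an Hr83 transgene, and the cause of this density was not tested.

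Forkhead-type sites were enriched at promoter peaks (24.6% against 18.5% of matched windows, log2 odds ratio 0.52 ± 0.09) and at the others, and fkh itself had the strongest peak. The motif GYAAAYA was found within 100 bp of the summit at 35.0% of 1711 peaks over 500 bp from a TSS against 17.2% of matched windows (log2 odds ratio 1.37 ± 0.12), at 50.1% against 16.6% in the strongest bin of 5 and 25.7% against 19.0% in the weakest, and at 37.2% from replicate 3 and 32.7% from replicate 4 alone. Of its hits within 250 bp, 36.5% lay within 50 bp of the summit. Base composition is argued against by random sets of scrambled 7-mers, 0% of which reached the same odds ratio in 1000 draws (highest 0.76), and chance choice among 8192 7-mers by a Bonferroni p of 8.37e-15 (Fisher's exact test) for GTAAACA, which ranked 12 while GAGA-type and CA-repeat 7-mers took the first 10 places. In all, 128 7-mers passed this correction, 4 of them of the forkhead type, so passing it does not single out forkhead-type sites. Binding of a forkhead factor at sites where Hr83-GFP was recovered is a candidate explanation that these lists cannot test; no biological explanation was tested.

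The lower frequency of the NR2E hexamer AAGTCA at peaks may be a property of the windows and not of this site. AAGTCA lay at percentile 26.7 among the 120 distinct 6-mers of its base composition, whose median log2 odds ratio was -0.07 and whose range was -0.84 to 0.66. Whether promoter sequence hides an excess of this site at other peaks is open: at the 1711 peaks over 500 bp from a TSS the log2 odds ratio was -0.43 in the planned draw of matched windows and -0.03 in another, and -0.162 ± 0.123 over 20 further draws, which leaves values up to 0.084 within 2 SE. No biological explanation was tested.

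The lower share of peaks on X could come from the single X of males in a pooled sample, if that lowers the deposited signal there. With X signals multiplied by 4/3 and the same threshold, X would hold 19.7% of 5185 peaks (18.7 to 20.8), above its 16.6% of TSSs and above the 13.2% observed. The whole pooled relaxed list, which is not cut at that threshold, held 12.4% of its regions on X. The rescaling overshoots, so it neither excludes this explanation nor fixes its size, and the proportion of males is not given in the sources used here. It also assumes a signal proportional to the number of X copies. The lists were called against a control alignment, and how that changed the signal on X is unknown.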
